A study of Mus musculus with 12 samples.

How the data were processed

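RNA of sorted and cultured mouse hepatic progenitor cells was hybridised to an Illumina mouse expression beadchip, 12 arrays in all, with 4 arrays each of cells given vehicle, IL-4 or IL-13. Per the labels, the culture medium contained IL-6, hepatocyte growth factor, epidermal growth factor and dexamethasone. Per the same labels, RNA was extracted with Trizol and cleaned on columns, and it was amplified with the Illumina TotalPrep kit and labelled with Cy3. Per the submitters' processing notes GenomeStudio 2011.1 was used, and its settings are not given in the sources used here. The deposited non-normalized table holds, per the file headers, a signal and a detection p-value for each of 45281 probes on each array. The values show the signal to be an intensity on a linear scale as the authors deposited it, not normalised between arrays and not background-subtracted. The deposited processed table holds log2 values. A comparison with the intensities showed that each array's values are the log2 of its intensities plus a constant (between 2.22 and 2.34) that brings every array to a median of 8.97, with no background correction. The array of each sample, and with it the chip and the position on it, was taken from the labels.

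The intensities were normalised in limma 3.58.1 (R 4.3.3) with neqc, which corrects the background from the detection p-values, adds an offset of 16, sets the arrays to common quantiles and takes log2. The offset pulls the fold changes of dim probes toward 0. Probes with a detection p under 0.05 on at least 4 of the 12 arrays were kept (19915). In the platform annotation 34885 probes had 1 gene symbol, 18 several and 10378 none, and 99.7% of the annotated probes were matched to current symbols by gene identifier. Of the kept probes 16680 had 1 symbol, and the 3226 without a symbol and 9 with several were left out of the gene counts. The probe with the highest mean log2 value stood for a gene, which left 10453 genes, 4185 of them with further probes. Among the named genes called with IL-4, 24 had further probes, 36 in number, of which 17 did not pass in the same direction in a fit of all probes. With IL-13 the numbers were 22, 37 and 11. Probes of near-identical genes, such as Chil3 and Chil4, Prl2c3 and Prl2c4, Ugt1a6a and Ugt1a6b and the hemoglobin genes, can bind each other's transcripts, so these genes are uncertain as separate measurements.

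The 3 comparisons (IL-4 with control, IL-13 with control, IL-13 with IL-4) were fitted in a single limma model over all 12 arrays with lmFit and eBayes, two-sided, and a gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05. Changes are differences of mean normalised log2 signal, with the model's standard error. A gene not detected on any array of a group has only a bound there, given as "at least N-fold": the brighter group's mean against the mean of, per array, the higher of the lowest signal among detected probes and the probe's own. The same bound is given for Chil4, Capn13 and Clca1, detected on some control arrays only, as was decided after their values were seen. For 27 gene lists covering cytokine signalling, epithelial and liver identity, metabolism, signalling pathways, stress and markers of other cell types, the changed members were counted. Lists with at least 5 measured members were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists. The test was repeated with the correlation estimated from the data and with fry. The text names, for each cytokine against control, the 10 largest rises and falls past the threshold with every treated array beyond every control array, and between the cytokines the 3 genes of smallest p in each direction, since none passed. It also names a fixed set of receptor, signalling and sort marker genes, and up to 2 rises and 2 falls per list and comparison. Further list members past the threshold are named as well, and these were chosen after their values were seen. The design, the lists, the naming rule and all alternatives other than the leaving out of control 4, IL-4 2 and IL-4 4 together or of the former pair, of the member of largest change (or Chil3 and Chil4 together) from each called list, and further settings for the correlation of the responses, were chosen before the data were examined. Alternatives were another background correction, offset, scaling, filter, probe rule, variance model, array weights and threshold, the submitters' processed values, the chip or the replicate number as a block, each chip alone, and each array left out in turn. Responses against the same controls were compared with unchanged groups simulated against those controls (100 simulated data sets) and with divided controls. The response score was compared with an exact permutation test over arrays. The fit was tested on simulated data with 200 changed genes among 10453. For IL-4 against control it recovered 36% of genes with the smallest simulated change, 0.32 on the log2 scale, and 98% of those changed 1.5-fold. For IL-13 against control it recovered 44% and 98%, and between the cytokines 44% and 100%, with 2.76%, 5% and 8.51% of the calls false. The simulated spread was normal, and the 200 changed genes made the adjusted threshold easier to pass. In the measured comparison of the cytokines no gene passed, and some differences over 1.5-fold missed the threshold. The simulated shares therefore do not tell which differences between the cytokines would have been called.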

Results

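Gene expression was measured in cultured mouse hepatic progenitor cells, epithelial precursor cells of the liver. They had been sorted as live EpCAM, CD24 and CD133 positive cells without the blood, endothelial and red cell antigens CD45, CD31 and TER119. The cells were deprived of serum for 24 hours and then received vehicle with bovine serum albumin, or IL-4 or IL-13 at 50 ng/mL. Each of the 3 groups had 4 arrays. How long the cytokines were present is not given in the sources used here. IL-4 and IL-13 are related type 2 cytokines that share a receptor chain and signal through the transcription factor STAT6. The design asks what each does to these cells and whether the responses differ. Between 18469 and 19869 of the 45281 probes were detected on an array (40.8 to 43.9%). The median raw signal lay between 99.1 and 107, and 10453 genes could be tested. Arrays of one group correlated across genes with r between 0.993 and 0.997, and 0 pairs held identical values. The first principal component, with 35.3% of the variance, parted all 8 treated arrays from the 4 control arrays. The second, with 15.7%, set control 4 and IL-4 2 apart from the rest. The 12 arrays lay on 2 chips with 2 arrays of every group on each. The position on the chip was fixed for each group, so that position and group cannot be told apart. Nothing says that the replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

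Some markers of the sorted cells were measured in every group. Krt19, a keratin of bile duct cells, had a normalised log2 signal of 11.34 ± 0.16 (SD, n = 4) in control arrays. Sox9, a transcription factor of duct and progenitor cells, lay at 10.12 ± 0.06, and the gate gene Cd24a at 7.83 ± 0.18. None of the 3 changed with a cytokine, with log2 differences between -0.18 (Sox9, IL-4) and 0.18 (Krt19, IL-4) (adjusted p from limma between 0.331 and 0.998). Prom1, which encodes CD133, was near the detection limit, with 1 of 4 control arrays and 3 of 4 IL-13 arrays detected. The probes of Epcam and of the hepatocyte gene Alb were detected on 0 arrays, as were those of Pecam1, which encodes CD31. As the cells had been sorted for EpCAM, a probe without signal may not mean that the transcript is absent. A single array, of IL-4, detected Ptprc, which encodes CD45. Of 23 macrophage and Kupffer cell markers 2 were measurable (Cd14 and Csf1r), of 18 lymphocyte markers 1 (Ltb), and of 22 stellate cell and fibroblast markers 4 (Des, Pdgfra, Ngfr and Acta2). These are too few for a test of these lists, and of these genes only Acta2 passed the threshold, with IL-13. The endothelial list, with 6 measured members, held 0 changed genes in either cytokine comparison (camera adjusted p = 0.531 with IL-4 and 0.520 with IL-13). Hemoglobin transcripts, in contrast, differed between single arrays. The mean of Hba-a1, Hbb-bt and Hbb-bs was 8.95 on IL-4 4, 6.77 on IL-4 2, 5.95 on control 4 and 5.36 on IL-4 1, against 4.40 to 4.80 on the other arrays. The erythroid list, with 5 measured members, did not pass its test with IL-4 (adjusted p = 0.0896) or IL-13 (0.888).

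IL-4 raised a small number of genes by large factors. Chil4, which encodes a chitinase-like protein secreted in type 2 inflammation, rose from a normalised log2 signal of 4.55 ± 0.38 (SD, n = 4) in control arrays to 13.19 ± 0.26 with IL-4 (adjusted p from limma = 4.36e-17). It was detected on 1 of 4 control arrays, so the size of the rise is only bounded, at least 360.1-fold by this probe and at least 59.7-fold by a dimmer Chil4 probe that was detected on 0 control arrays. Chil3, near-identical to Chil4, was not above background on any control array and was at least 26.9-fold higher with IL-4 (adjusted p = 1.44e-13). Igfbp5, which encodes a binding protein of insulin-like growth factors, rose 24.4-fold (log2 change 4.61 ± 0.17, SE; adjusted p = 4.71e-12). The falls were smaller, and the gene with the largest one, Lcn2, which encodes an iron-scavenging lipocalin, dropped 2.08-fold (log2 change -1.05 ± 0.20; adjusted p = 0.00433). In all, 363 of 10453 genes passed an adjusted p of 0.05, 225 higher and 138 lower with IL-4. Of these, 30 rose and 1 fell at least 2-fold. How the changed genes divided between higher and lower depended on the scaling of the arrays. With scaling to the 75th percentile 262 were higher and 92 lower. In the submitters' median-centred values, which also lack a background correction, 120 were higher and 294 lower. With arrays set to common quantiles but no background correction, 253 were higher and 170 lower. With the chip as a block 395 genes passed, within chip 1 255 and within chip 2 101. Without the 3 arrays of highest hemoglobin signal (control 4, IL-4 2 and IL-4 4), a choice made after the data were seen, 190 genes passed, of which 173 had passed in the same direction on all arrays.

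The other large rises with IL-4 fell on genes of several kinds. Capn13, a gene of the calpain proteases, was detected on 1 of 4 control arrays and on all IL-4 arrays and rose at least 6.41-fold (adjusted p = 1.22e-11). Cish, a feedback inhibitor of cytokine signalling of the SOCS family, rose 5.51-fold from a control level of 9.03 ± 0.19 (SD, n = 4; log2 change 2.46 ± 0.09; adjusted p = 3.78e-12). Hs3st1, which encodes a heparan sulfate sulfotransferase, rose 5.17-fold. Clca1, a goblet cell gene of mucus-producing epithelia, was detected on 3 of 4 control arrays and rose at least 4.12-fold. Egln3, which encodes a prolyl hydroxylase of hypoxia-inducible factors, rose 4.05-fold. The serine protease gene Prss35 rose 3.92-fold, the transmembrane protease gene Tmprss2 3.36-fold. Ccl17, which encodes a chemokine that attracts T helper cells, rose 3.78-fold from 6.11 ± 0.16 to 8.03 ± 0.25 (SD, n = 4). The adjusted p of these 6 genes lay between 1.77e-10 and 3.62e-07. Among the genes that fell, the proprotein convertase gene Pcsk6 changed by -0.82 ± 0.10 on the log2 scale (adjusted p = 3.67e-05). Nrep changed by -0.80 (0.000113), and Dio3, whose product inactivates thyroid hormone, by -0.76 (1.60e-06). The interferon-induced gene Ifit3 changed by -0.74 and the glucuronosyltransferase genes Ugt1a6a and Ugt1a6b, which share most of their sequence, by -0.74 and -0.68. Tafa5 changed by -0.73, the cornified envelope gene Sprr1b by -0.72, the granzyme gene Gzme by -0.71, and Crp, the gene of C-reactive protein, by -0.68. Uts2b, which encodes a urotensin peptide, changed by -0.72 (adjusted p = 0.0437), the cytokine gene Il11 by -0.62 (0.00127) and the acetylcholine receptor gene Chrna1 by -0.44 (0.0377). For Lcn2 and Chrna1 the IL-4 and control arrays overlapped. For every other gene named so far as past the threshold all 4 IL-4 arrays lay beyond all 4 control arrays. A further probe of Capn13, Egln3, Pcsk6 and Gzme, each of low signal (mean log2 4.50 to 4.60), did not pass with either cytokine, nor did 2 further probes of Ugt1a6a (mean log2 5.64 and 5.32).

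Genes of the cytokines' own receptors and of STAT6 targets were considered next. Il13ra1, which encodes a chain of the receptor that binds both cytokines, had a log2 difference of -0.36 ± 0.10 with IL-4 (adjusted p = 0.0512), and Stat6 one of 0.11 ± 0.12 (adjusted p = 0.776), neither past the threshold. Il4ra was detected on 0 arrays, Socs1 on at most 2, and Il2rg is not analysed here. Il13ra2, a decoy receptor of IL-13, was detected on 0 control and 1 IL-4 array. Its log2 difference of 0.19 did not pass (adjusted p = 0.334), and its bound, 0.889-fold, shows no rise. Of 19 measured receptor and JAK-STAT components, 2 rose with IL-4, the feedback inhibitors Cish and Socs2 (log2 change 0.27, adjusted p = 0.0498), and 0 fell. Adjusted over the list alone, 2 rose and 1 fell, and the list did not pass its test (camera adjusted p = 0.345). Of 19 measured STAT6 targets known from macrophages and lymphocytes, 8 rose and 0 fell with IL-4 (10 and 0 adjusted over the list alone). Besides Chil3, Chil4, Ccl17 and Cish these were Tgm2, the gene of tissue transglutaminase (log2 change 0.94), the monocyte chemokine gene Ccl7 (0.71), Gata3 (0.41) and Bcl6 (0.37). Arg1, a standard marker of IL-4 stimulated macrophages, was detected on 1, 2 and 2 arrays of control, IL-4 and IL-13 and did not pass the threshold with either. Retnla was detected on 0 arrays. The list passed its test upward (mean log2 change 1.11, with a median of 0.20 and means of 1.16 on chip 1 and 1.05 on chip 2; camera adjusted p = 1.29e-16). Most of that mean came from Chil4 and Chil3, which are uncertain as separate measurements. Without them, a choice made after the values were seen, the mean was 0.43 and the median 0.13 (adjusted p = 4.82e-09, and 0.0102 as adjusted p with an estimated correlation). With an estimated correlation the full list was the only one called with either cytokine (adjusted p = 0.00163 with IL-4 and 0.00315 with IL-13). The list of epithelial responses to type 2 cytokines also passed upward with IL-4, though not with an estimated correlation (adjusted p = 0.0601), with 2 of 10 measured members up (also 2 adjusted over the list alone). These were Clca1 and Slc26a4, which encodes the anion exchanger pendrin and was at least 1.37-fold higher. The list's mean log2 change was 0.36 (with a median of 0.19 and means of 0.40 on chip 1 and 0.32 on chip 2; adjusted p = 0.000288). Without Clca1 the mean was 0.17 (adjusted p = 0.0231).

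Of the 3 lists of lipid genes 2 passed upward with IL-4, neither with an estimated correlation (adjusted p = 0.0598 for cholesterol synthesis and 0.144 for fatty acid synthesis). Of 18 measured genes of cholesterol synthesis and uptake, 17 had a positive log2 difference with IL-4, but only Pmvk, which encodes phosphomevalonate kinase, passed the threshold (log2 change 0.49 ± 0.08; adjusted p = 0.00122). Adjusted over the list alone 5 rose and 0 fell. The list's mean log2 change was 0.15 (with a median of 0.11 and means of 0.14 on chip 1 and 0.17 on chip 2; adjusted p = 0.000154). Of 21 genes of fatty acid synthesis and lipid storage, 2 rose (4 adjusted over the list alone) and 0 fell: the malic enzyme gene Me1 (log2 change 0.94) and the lipid droplet gene Cidec (0.89). This list passed narrowly (mean log2 change 0.12, with a median of 0.06 and means of 0.13 on chip 1 and 0.10 on chip 2; adjusted p = 0.0455). Its call was lost without Me1 (0.163), with 75th percentile scaling (0.0631), without the 3 hemoglobin-rich arrays (0.0851) and without any 1 of control 2, control 4, IL-13 3 or IL-4 4 (at most 0.137). Of 21 fatty acid oxidation genes 1, Acadvl, rose (log2 change 0.28, adjusted p = 0.0498), and the list did not pass (adjusted p = 0.0896).

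The extracellular matrix and interferon lists passed downward with IL-4, but neither did with an estimated correlation (adjusted p = 0.270 and 0.175). Of 26 matrix and fibrosis genes, 2 fell, Col5a1, a fibrillar collagen gene (log2 change -0.39), and the growth factor gene Tgfb3 (-0.45). Another 2 rose, the integrin gene Itgb6 (0.63) and the thrombospondin gene Thbs1 (0.38), with 2 up and 3 down adjusted over the list alone. The list's mean log2 change was -0.13 (with a median of -0.15 and means of -0.14 on chip 1 and -0.11 on chip 2; adjusted p = 0.0291). Of 22 interferon response genes only Ifit3 fell and 0 rose (the same counts adjusted over the list alone). The list's mean log2 change was -0.11 (with a median of -0.09 and means of -0.06 on chip 1 and -0.16 on chip 2; adjusted p = 0.0455). Both calls were lost without the 3 hemoglobin-rich arrays (adjusted p = 0.0793 for each). The matrix call was also lost without control 2 or IL-4 2 (at most 0.112), and the interferon call without Ifit3 (0.102), with 75th percentile scaling (0.0631) and without any 1 of control 2, 3 or 4, IL-13 1 or 3 or IL-4 1 or 4 (at most 0.113).

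The remaining lists did not pass with IL-4, though single members did. Among 22 cholangiocyte markers 4 rose, the water channel gene Aqp1 (log2 change 0.82), the chloride-bicarbonate exchanger gene Slc4a2 (0.50), Krt18 (0.39) and Lgals3 (0.27). Another 2 fell, Krt7 (-0.36) and Sox4 (-0.34; list adjusted p = 0.135; 6 up and 3 down adjusted over the list alone). Among 16 hepatocyte markers Apoa1, the main apolipoprotein of high-density lipoprotein, rose (0.76; adjusted p = 0.0374; list adjusted p = 0.967). Of 36 cell cycle genes Ube2c alone fell (-0.28; list adjusted p = 0.627). In the inflammatory list of 23 genes Ccl7 and Vcam1 (0.44) rose and Lcn2 fell (list adjusted p = 0.163). Of 16 antigen presentation genes H2-K1 (0.36) and H2-T23 (0.30) rose (0.0896). The Notch list (12 genes) held a rise of Dtx4 (0.54) and a fall of Hey1 (-0.34; 0.777). The Wnt list (12) held a rise of Axin2, a feedback inhibitor of the pathway (0.40; 0.160), and the YAP list (19) no change (0.260). Of 24 unfolded protein response genes Atf3 (0.63), Chac1 (0.32) and Trib3 (0.29) rose (0.0896), and of 22 immediate early genes Atf3 and Klf4 (0.68; 0.481). The glycolysis and hypoxia list (19 genes) had 3 rises, Egln3, the glucose transporter gene Slc2a1 (0.54) and Pfkp (0.42). It had 4 falls, Pdk1 (-0.53), Ankrd37 (-0.40), Pfkl (-0.31) and Ndrg1 (-0.28; 0.832). The NRF2 and xenobiotic list (23) had rises of Aldh3a1 (1.11) and Gclm (0.37) and falls of Ugt1a6a and the transporter genes Abcc3 (-0.61) and Abcc4 (-0.35; 0.619). The p53 list (19) held a fall of Trp53inp1 (-0.39; 0.297) and the junction list (21) a rise of Pkp2 (0.50; 0.827). Adjusted over the list alone, rises and falls numbered 2 and 2 in the hepatocyte list, 0 and 1 in the cell cycle list, 2 and 0 in the fatty acid oxidation list, 4 and 2 in the inflammatory list, 2 and 1 in the antigen presentation list, 1 and 1 in the Notch list, 3 and 0 in the Wnt list and 0 and 0 in the YAP list. They numbered 3 and 0 in the unfolded protein response list, 6 and 1 in the immediate early list, 3 and 4 in the glycolysis list, 3 and 4 in the NRF2 list, 0 and 1 in the p53 list, 1 and 1 in the junction list, 0 and 0 in the endothelial list and 0 and 0 in the erythroid list. Median, mean and test did not all have the same sign for the hepatocyte (median -0.04, mean 0.03), glycolysis (-0.06, 0.05), inflammatory, junction, immediate early and endothelial lists. Apoa1 was detected on 2 of 4 control arrays and Cidec and Gata3 on 1, so the sizes of their rises are uncertain. Not all probes of these genes passed. With IL-4, 2 further probes each of H2-K1 (the brighter with a mean log2 of 7.60 and a log2 difference of 0.13, adjusted p = 0.717) and Vcam1 and 1 each of Acadvl, Itgb6, Klf4, Pkp2, Sox4, Trib3 and Trp53inp1 did not pass. With the mean of a gene's probes the IL-4 calls of H2-K1 (adjusted p = 0.118), Vcam1 (0.0688), Sox4 (0.192) and Acadvl (0.311) were lost. That of Uts2b was lost too (adjusted p = 0.0501), but Uts2b had no further kept probe. Its log2 change stayed at -0.72, and only the values of other genes in the fit and the adjustment differed. Several of these small changes hung on single arrays. Among genes of the naming rule, with arrays left out 1 at a time, the IL-4 call was lost without 11 of the 12 arrays for Acadvl, 10 for Socs2 and Trib3, 8 for H2-T23, 7 for Apoa1 and Sox4, 6 for Uts2b, Ugt1a6b, Thbs1 and Ankrd37. It was lost without 5 for Chrna1, Ube2c, Col5a1, Chac1 and Trp53inp1, 2 for Vcam1 and H2-K1 and 1 for Hey1 (adjusted p at most 0.149, for Socs2 without IL-4 1). Of the 62 IL-4 calls among the genes of the naming rule, 39 were kept without the 3 hemoglobin-rich arrays and 47 in the submitters' values. Fewer arrays alone can lose calls of that rule's genes, as 34 were kept within chip 1 and 31 within chip 2. The 9 other list members called with IL-4 lie outside that rule and were followed only after the values were seen. Of these 1 (Tgm2) was kept without the 3 hemoglobin-rich arrays and 4 in the submitters' values, and 6 were lost without at least 1 of the 12 arrays (adjusted p at most 0.144, for Pfkl without control 3). With the mean of a gene's probes the calls of Pfkl, Ndrg1 and Pfkp were lost (adjusted p = 0.533, 0.0534 and 0.137).

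**Figure D1:**
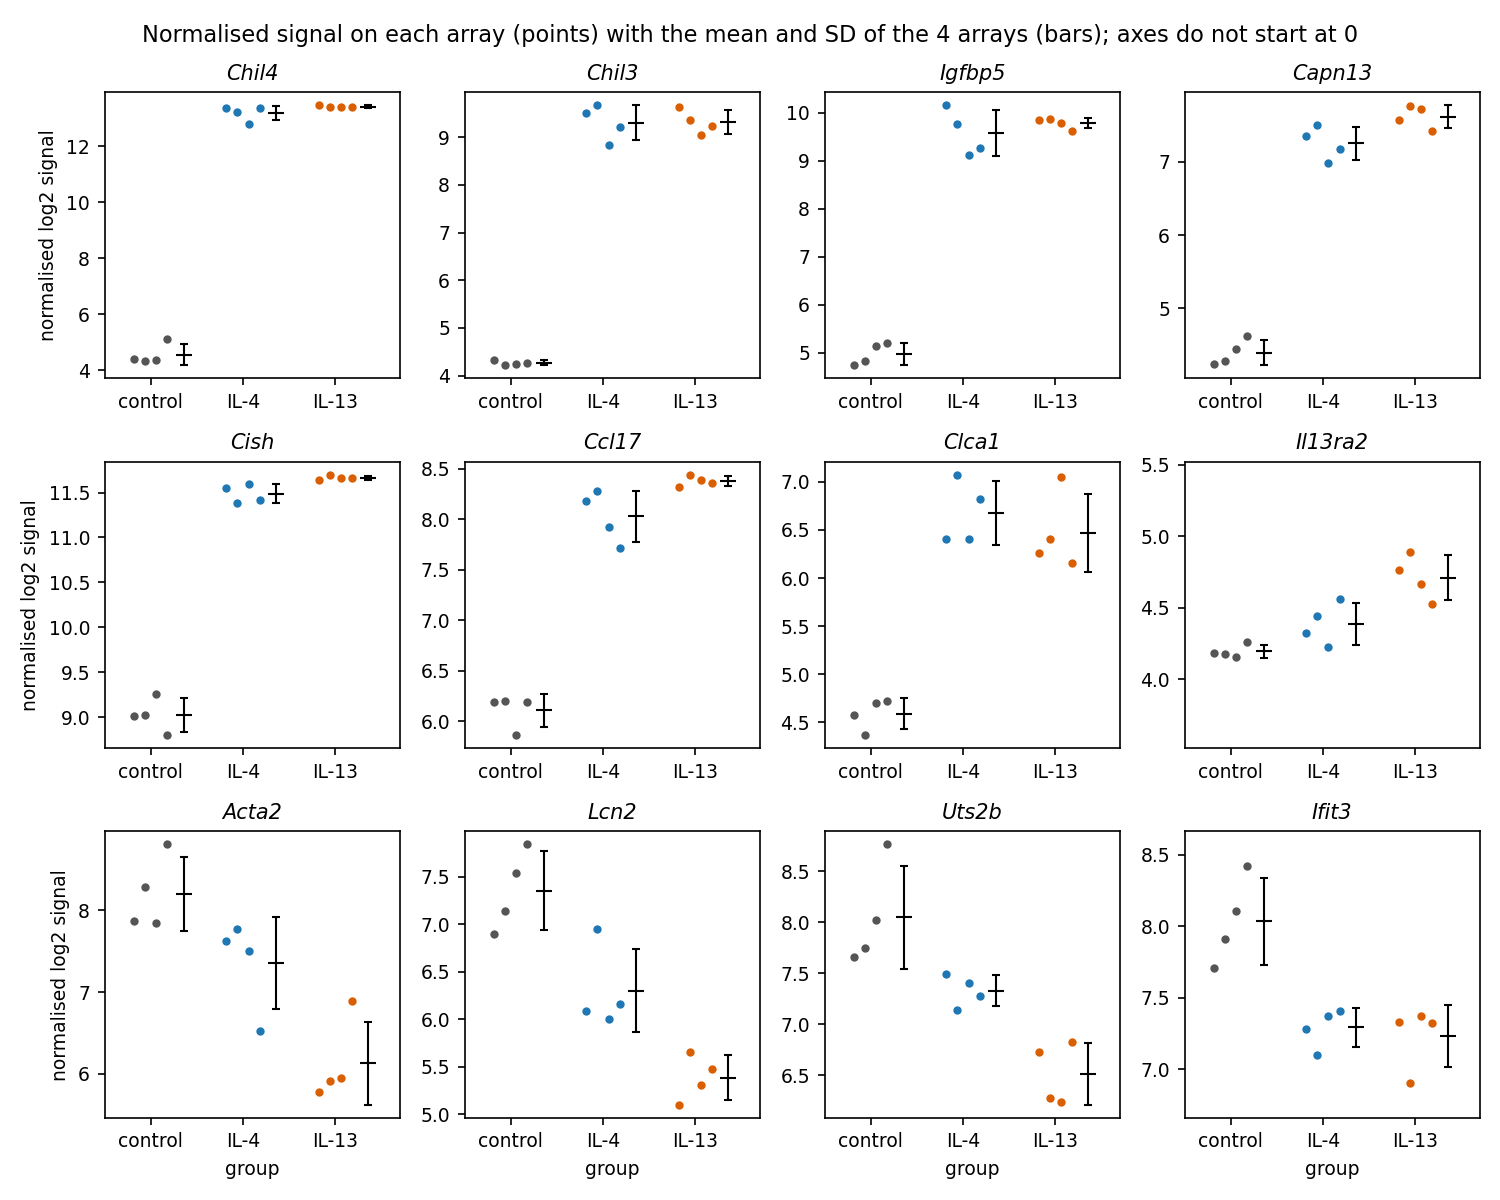
Normalised log2 signal of 12 genes (vertical axes, which do not start at 0) on each of the 4 control, 4 IL-4 and 4 IL-13 arrays (points, by group on the horizontal axis), with the mean and SD of each group as a bar beside its points. Chil4 rose from 4.55 in control arrays to 13.19 with IL-4 and 13.42 with IL-13, and Acta2 lay at 8.20, 7.36 and 6.13.

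IL-13 raised the genes that IL-4 raised most and lowered 3 genes, Acta2, Lcn2 and Uts2b, at least 2-fold. Chil4 rose to 13.42 ± 0.04 (SD, n = 4; adjusted p from limma = 2.80e-17), at least 421-fold by the brighter and at least 66.9-fold by the dimmer probe. Chil3 rose at least 27.1-fold (1.40e-13) and Igfbp5 28.1-fold (log2 change 4.81 ± 0.17; 1.81e-12). By the Igfbp5 probe detected on 0 control arrays the rise was at least 22.5-fold. Acta2, the gene of smooth muscle actin, fell 4.21-fold, from 8.20 ± 0.45 to 6.13 ± 0.51 (SD, n = 4; log2 change -2.07 ± 0.27; adjusted p = 6.54e-05). Its log2 difference of -0.85 ± 0.27 with IL-4 did not pass (0.109). Lcn2 fell 3.92-fold (log2 change -1.97 ± 0.20; 4.68e-06) and Uts2b 2.89-fold (-1.53 ± 0.19; 3.91e-05). In all, 599 of 10453 genes changed, 366 higher and 233 lower, with 43 rises and 3 falls of at least 2-fold. In the submitters' median-centred values 203 were higher and 406 lower. With the chip as a block 624 genes passed, within chip 1 243 and within chip 2 186, and without the 3 hemoglobin-rich arrays 514.

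The other large rises with IL-13 were those of Capn13 (at least 8.25-fold), Cish (6.23-fold, log2 change 2.64 ± 0.09), Hs3st1 (6.18-fold), Egln3 (5.03-fold), Prss35 (4.86-fold), Ccl17 (4.81-fold, to 8.38 ± 0.05) and Tmprss2 (4.00-fold), with adjusted p of at most 2.43e-10. Clca1 rose at least 3.57-fold (adjusted p = 1.14e-06). Beyond Acta2, Lcn2 and Uts2b, the largest falls with IL-13 were those of Il11 (log2 change -0.90 ± 0.10; adjusted p = 1.66e-05), Ugt1a6b (-0.89), Ugt1a6a (-0.88), Sprr1b (-0.87), Gzme (-0.87), Pcsk6 (-0.86) and Chrna1 (-0.82; 0.000114). Sprr1b and Gzme were each detected on 2 of 4 IL-13 arrays. For each of these genes, and for Chil4, Chil3 and Igfbp5, all 4 IL-13 arrays lay beyond all 4 control arrays. Of 3 further Acta2 probes, all of low signal (mean log2 5.03 to 5.29), 1 fell with IL-13 (log2 change -1.07; adjusted p = 0.00382). The other 2 gave log2 differences of -0.50 and -0.56 with IL-13 that did not pass (adjusted p = 0.0722 and 0.0875). Ifit3 (-0.80), Crp (-0.69), Dio3 (-0.66), Nrep (-0.63) and Tafa5 (-0.54), all lower with IL-4, fell with IL-13 as well (adjusted p at most 0.00547).

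The list of receptor and signalling genes passed its test upward with IL-13, but the call was lost without Cish and with an estimated correlation (adjusted p = 0.264). Of 19 measured components 5 rose and 0 fell (7 and 1 adjusted over the list alone). The list's mean log2 change was 0.24 (with a median of 0.03 and means of 0.23 on chip 1 and 0.25 on chip 2; camera adjusted p = 0.00333). Only 10 of the members had a positive log2 difference, and without Cish (2.64) the mean was 0.11 and the list no longer passed (adjusted p = 0.0522). The members that rose were Cish, Socs2 (log2 change 0.45, adjusted p = 0.000578), Il13ra2 and the kinase genes Jak3 (0.34) and Jak2 (0.30). Il13ra2 was detected on 0 control and 3 IL-13 arrays and was at least 1.11-fold higher (0.00126). Il13ra1 had a log2 difference of -0.33 ± 0.10 (0.0525) and Stat6 one of 0.23 ± 0.12 (0.354), neither past the threshold. Of the 19 STAT6 targets 9 rose, the 8 that rose with IL-4, among them Tgm2 (2.38-fold), and the vascular endothelial growth factor receptor gene Flt1 (log2 change 0.57). The member that fell was the mannose receptor gene Mrc1, detected on 3 control and 0 IL-13 arrays (at least 1.16-fold lower; 0.0280). Adjusted over the list alone, 10 rose and 1 fell. Over the list the mean log2 change was 1.17 (with a median of 0.22 and means of 1.18 on chip 1 and 1.16 on chip 2; adjusted p = 5.37e-14). Without Chil4 and Chil3 the mean was 0.49 and the median 0.21 (adjusted p = 1.08e-07, and 0.0180 as adjusted p with an estimated correlation). Of the 10 epithelial type 2 response genes 4 rose (also 4, with 1 fall, adjusted over the list alone). These were Clca1, Slc26a4 (at least 1.90-fold), Il13ra2 and the transcription factor gene Foxa3 (0.42). Over these genes the mean log2 change was 0.39 (with a median of 0.10 and means of 0.40 on chip 1 and 0.38 on chip 2; adjusted p = 0.00145, and 0.0635 as adjusted p with an estimated correlation). Without Clca1 it was 0.23 (adjusted p = 0.0165).

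The lists of cholangiocyte markers, cholesterol genes and fatty acid synthesis also passed upward with IL-13, but none did with an estimated correlation (adjusted p = 0.0635 for each). Of 22 cholangiocyte markers 4 rose, Aqp1 (log2 change 0.93 ± 0.08), Slc4a2 (0.70), Krt18 (0.46) and Lgals3 (0.25). Another 2 fell, the mucin gene Muc1 (-0.68) and Krt7 (-0.44), with 5 up and 2 down adjusted over the list alone. The list's mean log2 change was 0.13 (with a median of 0.15 and means of 0.10 on chip 1 and 0.17 on chip 2; adjusted p = 0.00927, 0.0748 with 75th percentile scaling and 0.0602 without Aqp1). Of 18 cholesterol genes 1, Pmvk (0.37), rose (3 adjusted over the list alone). The mean log2 change was 0.15 (with a median of 0.15 and means of 0.11 on chip 1 and 0.18 on chip 2; adjusted p = 0.00223). Of 21 fatty acid synthesis and storage genes 4 rose, Cidec (1.18), Me1 (0.88), Acss2 (0.44) and Scd2 (0.39), with 8 up and 1 down adjusted over the list alone. The mean log2 change was 0.17 (with a median of 0.08 and means of 0.16 on chip 1 and 0.18 on chip 2; adjusted p = 0.00454). The cell cycle list passed downward by a small mean (mean log2 change -0.08, with a median of -0.07 and means of -0.11 on chip 1 and -0.04 on chip 2; adjusted p = 0.0321, and 0.485 as adjusted p with an estimated correlation). Only Ube2c, a ubiquitin-conjugating enzyme gene of mitosis, passed among its 36 genes (-0.25; adjusted p = 0.0434) and 0 did adjusted over the list alone. That list call was lost without Ube2c (adjusted p = 0.0631) and without control 1, control 2 or IL-13 2 (adjusted p at most 0.142).

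Single genes of lists that did not pass also changed with IL-13. Among the 16 hepatocyte markers Apoa1 rose (log2 change 1.23 ± 0.19) and Trf (-0.32), Fah (-0.29) and Nr1h4, the gene of the bile acid receptor FXR (-0.29), fell (list adjusted p = 0.541). Of the 26 matrix genes 4 fell, Acta2, Loxl1 (-0.45), Tgfb3 (-0.33) and Timp1 (-0.31). Another 2 rose, Itgb6 (0.77) and Thbs1 (0.40; list adjusted p = 0.300; 4 up and 6 down adjusted over the list alone). Col5a1 had a log2 difference of -0.26 (0.140). In the inflammatory list (23 genes) the chemokine genes Cx3cl1 (0.68) and Ccl7 (0.67), Vcam1 (0.52) and Relb (0.32) rose and Lcn2 fell (0.263). In the interferon list Ifit3 fell (0.0672), and in the antigen presentation list H2-T23 rose (0.31; 0.0731). In the Notch list Dtx4 rose (0.79) and Hey1 fell (-0.41; 0.512). In the Wnt list Axin2 (0.61) and Lgr5, a stem cell marker not detected in control arrays (at least 1.13-fold), rose (0.0731). The YAP and p53 lists held 0 changed genes (0.358 and 0.520), and the unfolded protein response list rises of Atf3 (0.84), Trib3 (0.34) and Chac1 (0.30; 0.354). The fatty acid oxidation list held a rise of Acadm (0.36; 0.286), and the junction list rises of Pkp2 (0.54), Llgl2 (0.42) and Esrp2 (0.34) and a fall of Cldn6 (-0.62; 0.300). In the glycolysis and hypoxia list Egln3, Slc2a1 (0.74) and Pfkp (0.46) rose and Ankrd37 (-0.48), Pdk1 (-0.38) and Pfkl (-0.29) fell (0.888). In the NRF2 list Aldh3a1 (1.17) and Gclm (0.40) rose and Ugt1a6a, Abcc3 (-0.71), Abcc4 (-0.44) and Cyp1b1 (-0.41) fell (0.512). In the immediate early list Atf3, Klf4 (0.78), Fos (0.45) and Hspa1a (0.45) rose and Ier3 (-0.35), Ier5 (-0.29) and Dusp6 (-0.29) fell (0.358). Adjusted over the list alone, rises and falls numbered 4 and 4 in the hepatocyte list, 1 and 0 in the fatty acid oxidation list, 4 and 3 in the inflammatory list, 0 and 1 in the interferon list, 1 and 0 in the antigen presentation list, 3 and 3 in the Notch list, 2 and 0 in the Wnt list and 2 and 1 in the YAP list. They numbered 3 and 0 in the unfolded protein response list, 5 and 4 in the immediate early list, 3 and 3 in the glycolysis list, 4 and 6 in the NRF2 list, 0 and 0 in the p53 list, 3 and 1 in the junction list, 0 and 0 in the endothelial list and 0 and 0 in the erythroid list. With IL-13, median, mean and test did not all have the same sign for the hepatocyte (median -0.07, mean 0.03), glycolysis (-0.04, 0.10) and erythroid lists. The 2 further probes of Vcam1 and 1 of Itgb6 did not pass with IL-13, and the Vcam1 call was lost with the mean of its probes (adjusted p = 0.0620). Among genes of the naming rule, with arrays left out 1 at a time, the IL-13 call was lost without 10 of the 12 arrays for Ube2c, 7 for Ier5, 6 for Chac1, 5 for Tgfb3 and Pdk1, 4 for Mrc1, Nr1h4, Thbs1 and H2-T23, 3 for Lgr5 and Llgl2 and 1 for Trf (adjusted p at most 0.110, for Ube2c without control 3). Of the 71 IL-13 calls among the genes of the naming rule, 64 were kept without the 3 hemoglobin-rich arrays and 62 in the submitters' values. The 22 other list members called with IL-13 lie outside that rule and were followed only after the values were seen. Of these 13 were kept without the 3 hemoglobin-rich arrays and 10 in the submitters' values, and 12 were lost without at least 1 of the 12 arrays (adjusted p at most 0.133, for Cyp1b1 without IL-13 2). With the mean of a gene's probes the calls of Jak3, Timp1, Pfkl, Esrp2 and Dusp6 were lost (adjusted p = 0.216, 0.0774, 0.246, 0.121 and 0.0808).

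**Figure D2:**
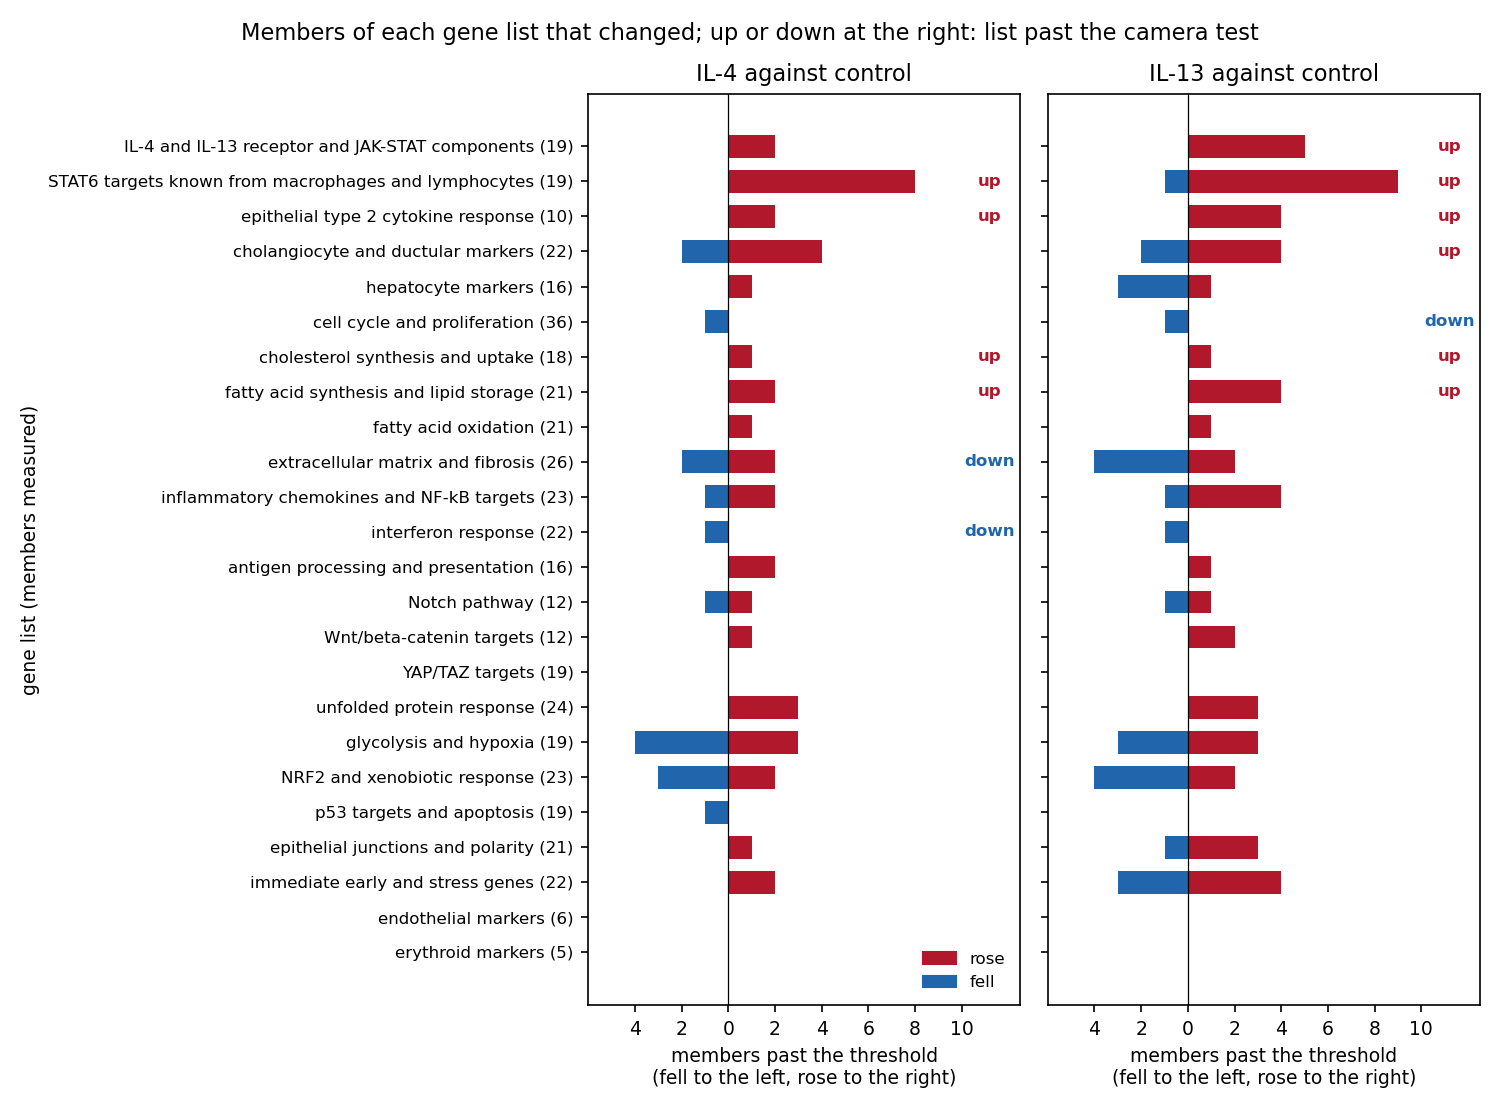
Members of each of the 24 tested gene lists that rose (red, to the right) or fell (blue, to the left) past an adjusted p of 0.05 with IL-4 (left panel) and IL-13 (right panel); the number measured stands after each list's name, and up or down marks lists past the camera test. The STAT6 target list had 8 rises with IL-4 and 9 with IL-13 among 19 genes.

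Between the cytokines, limma called 0 genes different. In all 852 genes had an unadjusted p under 0.05 where chance gives 523 (smallest adjusted p 0.133). With single arrays left out that number ranged from 560 (without IL-13 3) to 1080 (without control 4). It was 931 within chip 1 and 533 within chip 2. Genes are not independent of each other, and the excess over 523 was not tested. The genes nearest to a call, named because they had the smallest p in each direction, were Slc26a4 (log2 difference 0.47 ± 0.09), the chitinase-like gene Chil5 (0.45 ± 0.09) and the phosphodiesterase gene Pde2a (0.52 ± 0.10), higher with IL-13. In the other direction they were Tmed2 (-0.46 ± 0.08) and the prolactin family genes Prl2c3 (-0.67 ± 0.12) and Prl2c4 (-0.71 ± 0.13), and all had an adjusted p of 0.133 to 0.134. Against control, Chil5, not detected on control arrays, was at least 1.04-fold higher with IL-4 and at least 1.42-fold with IL-13. Pde2a rose by 0.46 and 0.97 on the log2 scale. The IL-4 call of Chil5 was lost without any 1 of 6 arrays (adjusted p at most 0.0780) and that of Pde2a without IL-4 4 (0.0548). Acta2 had a log2 difference between IL-13 and IL-4 of -1.23 ± 0.27 (95% interval -1.80 to -0.66; adjusted p = 0.246). Lcn2 had one of -0.92 ± 0.20 (0.246) and Uts2b one of -0.81 ± 0.19 (0.309), so none of these differences passed. Within chip 1 alone Acta2 passed (log2 difference -1.86; adjusted p = 0.000419), with 0 genes past within chip 2 and 0 with the chip as a block. With an intensity trend and a robust prior limma called Prl2c3 (adjusted p = 0.0180) and Prl2c4 (0.0283). Without IL-13 4 it called Slc26a4 (0.0322), and without IL-13 1 Hid1, outside the naming rule and chosen after its value was seen (log2 difference 0.56, 0.0338). The 95% interval of a gene's difference reached 0.191 to either side on the log2 scale for the median gene, so differences smaller than this cannot be excluded for such a gene. As a list, the receptor and JAK-STAT components were higher with IL-13 (mean log2 difference 0.13, with a median of 0.10 and means of 0.17 on chip 1 and 0.09 on chip 2; camera adjusted p = 0.00115, and 0.309 as adjusted p with an estimated correlation). Of its members 0 passed over all genes and 1, Il13ra2 (0.32), adjusted over the list alone. Without the 3 hemoglobin-rich arrays this call was lost (adjusted p = 0.0516). The erythroid list did not pass between the cytokines (adjusted p = 0.134), although 2 members, Hba-a1 and Hbb-bt, were lower with IL-13 adjusted over the list alone. The remaining lists did not pass either. Adjusted over the list alone, single members of them did: Tgm2, Slc26a4 and Il13ra2 were higher and Acta2 and Lcn2 lower with IL-13, while over all genes none passed. With the chip as a block every list called on all arrays stayed past its test, with adjusted p of at most 0.0409 for IL-4, 0.0317 for IL-13 and 0.00152 between the cytokines. Every list whose loss is not named above stayed past its test without its member of largest change, a choice made after the values were seen (adjusted p at most 0.0455). Median, mean and test did not all have the same sign for the epithelial type 2, hepatocyte and interferon lists here.

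The responses to the cytokines overlapped. Of the 363 genes changed with IL-4, 82.4% also changed with IL-13. In all 203 genes, among them Chil4, Igfbp5 and Cish, were higher with both (7.88 in independent lists). Another 96, among them Lcn2, Pcsk6 and Ifit3, were lower with both (3.08 in independent lists), and 0 were called in opposite directions. IL-13 alone called 300 genes and IL-4 alone 64, which does not show that these genes differ between the cytokines, since no gene passed that test. Across the 10453 genes, which are not independent replicates, the log2 changes correlated with Pearson's r = 0.845 and Spearman's rho = 0.622. Both comparisons use the same control arrays, and simulated groups without any effect gave 0.50 and 0.479, and limma called 0 genes in both in each of 20 simulated data sets. With each response set against its own 2 of the 4 controls, over all 6 ways to divide them, r lay between 0.571 and 0.731 and rho between 0.155 and 0.406. The covariance of the changes was 0.0396, against 0.00460 in the simulated groups, a difference of 0.035. It lay between 0.0314 and 0.0365 with divided controls. With divided controls, 94 to 112 genes were higher with both and 19 to 26 lower with both, against 2.21 to 3.22 and 0.316 to 0.665 in independent lists. Genes changed the same way by both numbered 159 within chip 1, 89 within chip 2 and 170 without the 3 hemoglobin-rich arrays. Within chip 1 r was 0.803 and within chip 2 0.801.

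**Figure D3:**
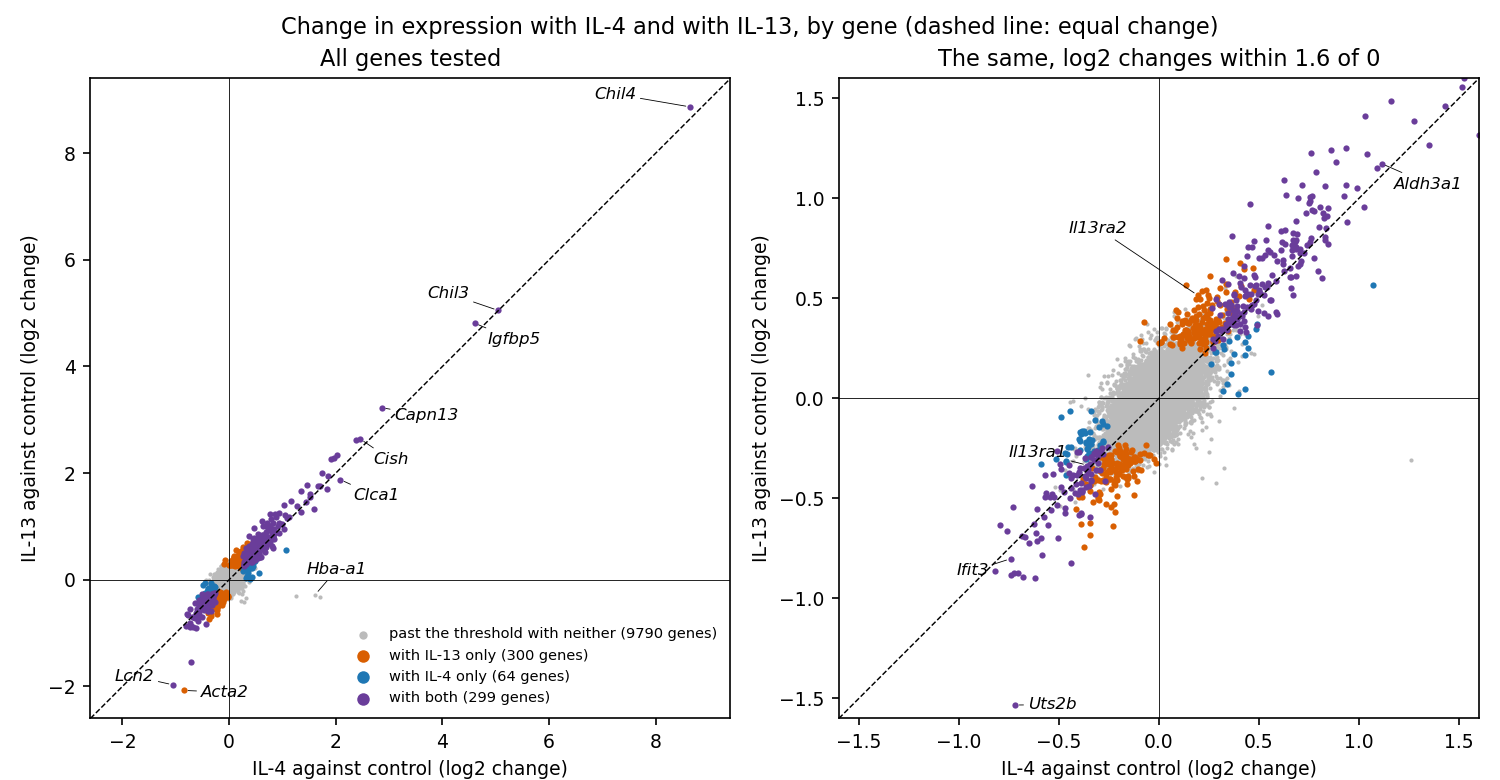
Log2 change with IL-4 (horizontal axis) against log2 change with IL-13 (vertical axis) of 10453 genes, each a point, over the full range (left) and near 0 (right), coloured by the comparisons in which the gene passed; the dashed line marks equal change. The 299 genes that passed with both lie along the line, with Chil4 at 8.64 and 8.87.

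The size of the responses was compared with a score per array, the mean change from the control mean over 642 genes that changed when all treated arrays were set against control, each counted in its direction. The score was 0.469 ± 0.0318 with IL-4 and 0.538 ± 0.0206 with IL-13 (SD, n = 4). All 4 IL-13 arrays lay above all 4 IL-4 arrays (difference 0.0698, ratio 1.15; two-sided exact permutation p = 0.0286, the smallest the design can give). Over the 367 genes that rose the difference was 0.0872 and over the 275 that fell 0.0466. The difference was 0.0349 within chip 1 and 0.133 within chip 2, where the smallest exact p is 0.333. It was 0.0667 with the chip as a block (exact p = 0.0556, the smallest possible there) and 0.0657 without the 3 hemoglobin-rich arrays (0.0667, again the smallest possible). It did not pass without control 4 (0.0486, exact p = 0.114), without IL-13 2 (0.0705, 0.0571), without IL-13 3 (0.0645, 0.0571) or in the submitters' values (0.0298, 0.0571).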

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

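The tests of the hemoglobin signal, of the dependence of the response score on single arrays and of the 6 abundant mesenchymal and smooth muscle genes were chosen only after the result was seen.

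To ask whether chance assignment of arrays gives such counts, the 8 arrays of each comparison were divided in all 35 ways into 4 and 4. Only 1 division, the real one, gave the 363 genes called with IL-4, and the highest other gave 1. Likewise 1 division gave the 599 genes called with IL-13, and the highest other gave 1. Both counts are thus unlikely from a chance division of the arrays, though 1 in 35 is the smallest share possible here. The other divisions mix treated and control arrays, which widens the spread within their groups and lowers their counts. A difference between the groups other than treatment, such as array position, is not tested in this way. Between IL-13 and IL-4 the real count is 0, so all 35 divisions give at least as many whatever the data (highest other 1), and nothing about chance follows there.

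The hemoglobin genes Hba-a1, Hbb-bt and Hbb-bs had a mean log2 signal of 8.95 on IL-4 4, 6.77 on IL-4 2 and 5.95 on control 4. Treatment with IL-4 is argued against as the whole cause, since control 4 received none and lay above IL-4 1 (5.36) and IL-4 3 (4.68). Only 2 of the 4 IL-4 arrays lay above all other arrays. All 4 did lie above control 1, control 2 and control 3 (4.48 to 4.64), IL-4 3 only just and below IL-13 2 (4.80). A share of IL-4 in the signal thus stays open. For IL-4 4, the difference that sets control 4 and IL-4 2 apart on the second principal component is argued against as the whole cause, since IL-4 4 lay at -2.68 there, more than 2 SD of the 9 other arrays from the mean of that pair (-12.85), but just below the lowest of the 9 (-2.42; mean 3.15, SD 3.88), so that a smaller share stays open. RNA of red cells or erythroblasts, which the TER119 gate would remove, may be the source, but the other erythroid markers differed on IL-4 4 by a median of 0.0765 on the log2 scale and cannot decide, because all except Tfrc lay near the detection limit.

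The larger response score with IL-13 than with IL-4 is small (difference 0.0698). IL-4 2, an array with hemoglobin signal, had the highest score of the IL-4 arrays (0.501), so a low score there does not explain the difference. Leaving it out could hardly narrow the difference (0.0796 without it, exact p = 0.0286) and so cannot test dependence on that array. IL-4 3 had the lowest score (0.425), and without it the difference was 0.0487 (exact p = 0.0286). Dependence on control 4 stays open, since without that array the difference was 0.0486 (exact p = 0.114), lower but still above 0. Array position cannot be told apart from the cytokine, as 0 positions on the chip hold both. A stronger response of these cells to IL-13 at the same mass concentration is the biological candidate explanation, and it stays open as well.

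Acta2 fell with IL-13 from 8.20 ± 0.45 to 6.13 ± 0.51, with IL-13 4 (6.89) apart from the other IL-13 arrays (mean 5.88). Fewer mesenchymal or smooth muscle cells in the IL-13 wells could also lower Acta2. Of 6 abundant genes of such cells (Col1a1, Col1a2, Col3a1, Tagln, Myl9 and Cnn1) 0 were detected on 2 or more control arrays, while Acta2 was detected on all. These 6 were chosen after the data were seen, and a probe that works poorly would also give no signal. Among the planned mesenchymal genes Sparc was detected on 4 control arrays and Des on 2, so such cells cannot be excluded. The planned test on matrix genes rested on a single gene, Sparc, with a log2 difference of -0.16, and decides nothing alone. A lower level of contractile genes and targets of serum response factor in the progenitor cells may accompany the fall of Acta2, but over 10 such genes the median difference was -0.0971. That meets the bound set beforehand for excluding it, but by less than the standard error over the genes. The bound as set held no such margin, and with the margin the explanation is left open.

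Single arrays stood apart from the other arrays of their group, judged by the gap to the nearest value against the range, in 25 of 263 groups of 4 values, where chance gives about 1 in 20, or 13.2. That share holds for independent, normally distributed values, which signals near background need not be. Control 4 stood apart 5 times, with log2 signals of 5.12 for Chil4 (other controls 4.36), 4.77 for Prom1 (4.38), 8.16 for Ccl7 (7.41), 6.91 for Cx3cl1 (7.60) and 9.86 for Slc2a1 (10.25). Among the other control arrays, control 1 stood apart for Slc26a4 (4.49, others 4.36) and Gclm (10.19, 10.03), control 2 for Sprr1b (6.04, 5.34) and Hey1 (6.63, 6.74), and control 3 for Ccl17 (5.86, 6.19). Slc26a4 was detected on 0 control arrays and Chil4 and Prom1 on 1 each, so their control values lay largely at background. IL-4 2 stood apart for Lcn2 (6.95, other IL-4 arrays 6.08), Slc4a2 (10.71, 10.93) and Me1 (9.60, 9.36), and IL-4 4 for Pdk1 (5.74, 6.07) and Pkp2 (9.35, 9.48). IL-4 1 stood apart for Prss35 (8.0, 8.29), Cldn6 (8.19, 8.50) and the number of probes detected (19869, 19192), and IL-4 3 for Nr1h4 (8.01, 7.88). IL-13 2 stood apart for Hs3st1 (10.40, other IL-13 arrays 10.17) and Ifit3 (6.91, 7.34), IL-13 3 for Chrna1 (5.17, 5.40), and IL-13 4, besides Acta2, for Krt7 (9.20, 9.08) and Cx3cl1 (7.93, 8.16).

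Outside the gene counts, 129 of 3226 detected probes without a gene name in the annotation used changed with a cytokine (limma adjusted p under 0.05), 60 with IL-4 and 117 with IL-13, and the largest log2 change was 3.46 with IL-4 and 3.54 with IL-13.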

How the results depend on the processing

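The leaving out of the hemoglobin-rich arrays and of the member of largest change from each called list, and several settings for the correlation of the responses, were chosen only after the data were seen. Of the genes called against control 0 with IL-4 and 0 with IL-13 took the opposite sign in any of 29 alternatives with 1 value for each gene, some of which cannot alter the estimate, and no called list reversed. The balance of the called genes did reverse in the submitters' values, from 225 higher and 138 lower to 120 and 294 with IL-4 and from 366 and 233 to 203 and 406 with IL-13. Across settings other than single arrays left out, 4420 named-gene results kept their side of the threshold, 354 lost and 59 gained a call, and of gene list results 483 kept, 28 lost and 7 gained. Many of the results kept were never calls, so these totals understate how often a call was lost. Of 255 named-gene results on all arrays, 62 were calls with IL-4, 71 with IL-13 and 0 between the cytokines. Of 72 list results 6, 7 and 1 were. The count with IL-4 (363) was 101 within chip 2, 204 at an adjusted p of 0.01, 125 with a fold of at least 1.5 and 190 without the 3 hemoglobin-rich arrays; that with IL-13 (599) was 243 and 186 within the chips, 316 at 0.01 and 154 with the fold. Fewer arrays or a stricter threshold are part of each of these settings. With single arrays left out the counts ranged from 251 to 442 with IL-4, 409 to 593 with IL-13 and 0 to 1 between them (0 on all arrays; 1 within chip 1, 2 with a trend and robust prior). Lists called with IL-4 (6), IL-13 (7) and between them (1) were 1, 1 and 0 with an estimated correlation, 3, 7 and 0 without the 3 arrays, and 3 (without control 2) to 9, 6 to 8 and 1 to 3 with single arrays left out (the highest without IL-13 3, and 2 without IL-13 1, IL-4 1 or IL-4 2). Fry, which asks whether a list's genes move one way or, mixed, in either direction and compares them with no other genes, called 20 and 21 lists mixed, and between the cytokines 0 one way; without control 4 and IL-4 2 camera called 2 there. The correlation of 0.845 was 0.803 and 0.801 within the chips, 0.579, 0.574, 0.731, 0.571, 0.713 and 0.696 with divided controls, and 0.812 to 0.855 with single arrays left out. The 299 genes changed the same way by both were 159 and 89 within the chips, 170 without the 3 arrays, 135, 131, 123, 127, 115 and 131 with divided controls, and 225 to 317 with single arrays left out. The response score difference of 0.0698 was 0.0298 in the submitters' values, 0.0349 and 0.133 within the chips and 0.0486 (without control 4) to 0.0892 with single arrays left out. The cause was not tested for the changes with the submitters' values, with single arrays left out, with the trend and with fry. Replicate numbers gave no clear pairing of the arrays: of 12 same-numbered pairs 5 deviated together with r over 0.1 (lowest -0.146), and 4 of 12 arrays correlated best with their own number. The median r was 0.0885 for the same number, -0.0184 for other numbers and 0.0474 for the same chip, so a weak pairing cannot be excluded. The replicate block gave 358, 600 and 0 genes, 2 lists between the cytokines and a score difference of 0.0655. The median raw signal was 1.18 to 1.23 times the lowest on each array, which limits what dim genes can show.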

Other observations

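Genes outside the naming rule and the lists, chosen only after their values were seen, changed with both cytokines in the same direction. Spink4, a serine protease inhibitor gene of goblet cells, and the phospholipase gene Pla2g4c were not detected on any control array and were at least 2.97-fold and 2.97-fold higher with IL-4 and at least 3.15-fold and 2.7-fold higher with IL-13. The carbonic anhydrase gene Car2 rose by 1.71 ± 0.13 (SE) on the log2 scale with IL-4 and 1.76 ± 0.13 with IL-13, and Elf3, an epithelial transcription factor gene, by 1.67 ± 0.12 and 1.76 ± 0.12. Other rises with IL-4 and IL-13 were those of Shisa2 (1.46 and 1.78), the cytokine gene Il24 (1.43 and 1.46), the coactivator gene Ppargc1b (1.28 and 1.39), the complement factor gene Cfi (1.16 and 1.49), Reg1 (1.35 and 1.27) and the vitamin D receptor gene Vdr (0.83 and 1.06). Falls included those of the collagen gene Col16a1 (-0.65 and -0.72), the activin antagonist gene Fst (-0.59 and -0.78), the fatty acid receptor gene Ffar4 (-0.59 and -0.70), the peroxisomal thiolase gene Acaa1b (-0.63 and -0.63) and the adhesion molecule gene Mcam (-0.57 and -0.59). The adjusted p from limma of these genes was at most 0.00718. None lost its call without any 1 of the 12 arrays or in the submitters' values, but without the 3 hemoglobin-rich arrays Mcam did with IL-4 (adjusted p = 0.167).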
